A study of Mus musculus with 6 samples.

How the data were processed

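The series measured mRNA levels in tissue of newborn mice (postnatal day 1) with Affymetrix 3' expression arrays, on biotin-labelled material prepared from total RNA. There were 6 arrays in 2 groups of 3, wildtype and D6/Zbtb20S transgenic, and each array held RNA pooled from 7 animals, per the labels' protocols. The groups were taken from the genotype and titles in the labels, and the wildtype animals were littermates of the transgenic ones, per the series' design text. The sources do not say whether the 3 pools of a group came from separate litters, so p-values measure the spread between these pools.

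The deposited table held 1 log2 value per probe set and array, and RMA and limma are the tools named in the submitters' processing notes, with no version, order or annotation given in the sources used here. RMA corrects background, normalizes arrays to each other and summarises the probes of a probe set. The scale was taken as log2 from the range of the values, since natural logs of that size would exceed the range of the scanner. Array medians lay between 3.83 and 3.97, so the scaling last applied, and any centring of arrays, stays unknown. Individual medians were 3.83, 3.87 and 3.91 for wildtype replicates 1, 2 and 3, and 3.86, 3.83 and 3.97 for D6/Zbtb20S replicates 1, 2 and 3. Probe-level files and detection calls were not used here. RMA compresses changes near the floor, so the fold of a gene whose group mean lies under the array median may be too small. The number of arrays limits the precision of every value.

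The table held 45101 probe sets. The array's 64 control probe sets were left out, and 45037 were tested. Gene names came from the platform annotation supplied with the table: 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not named in it. Of the named probe sets, 34741 matched a gene of the GRCm38.p6 gene table by gene ID, and 0 symbols changed. That table was used for names only, and no coordinates are printed because the sources name no build. Probe sets with several symbols gave no gene name. For the 18193 genes, a gene with several probe sets (9010 genes) was represented by the probe set with the highest mean over all 6 arrays. Probe sets whose names end in _s_at or _x_at can match more than 1 transcript.

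Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, 1 coefficient per group and no covariates) on the deposited log2 values, with Benjamini-Hochberg adjustment over all genes, or over all probe sets where probe sets are counted. The threshold was an adjusted p under 0.05. Every adjusted p printed for a gene is from this limma fit unless another test is named. Changes are D6/Zbtb20S minus wildtype, and ± after a change is its standard error from the moderated fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

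Before the data were examined, 30 gene lists with 528 members (502 distinct genes) were fixed from textbook markers of hippocampal fields, the dissected areas, cortical layers, other cell types and neighbouring regions, and from pathways. Of the members, 494 were measured (470 distinct genes). The 29 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry, a rotation test. A list of 12 genes (10 measured) was written from memory as those singled out by the study, may not match it exactly, and is not taken as independent evidence of its own direction. Nor are the layer lists that hold its members.

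The genes named in the text follow a rule also fixed before the data were examined: Zbtb20, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between groups, and up to 4 passing members per list, or 2 members with the smallest p where none passed. In the layer, hippocampal and study lists every passing member could be named. Genes and families outside this rule are said to be chosen after their values were seen.

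The fit and the list test were checked on data simulated for the comparison of D6/Zbtb20S with wildtype over 18193 genes, with the spread of the real arrays and 200 genes changed. Of genes changed by 0.5 on the log2 scale 46% were recovered, and of genes changed by 1, 91%. False calls made up 4.86% of calls, and 0 genes were called where none had been changed. At an unadjusted p under 0.05, camera called 1.5% of 200 unshifted lists of independent genes.

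The alternatives fixed beforehand were a replicate block, leaving out each array in turn, equal array medians, quantile normalization, array weights, an intensity trend, a filter on dim probe sets (above the array median in at least 3 arrays), the mean of a gene's probe sets, thresholds of 0.01 and 0.1, an ordinary linear model without empirical Bayes, and, for the lists, an estimated correlation, fry and removal of the study's genes.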

Results

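Gene expression was measured on postnatal day 1 in 2 neighbouring cortical areas, the retrosplenial cortex and the subiculum, dissected together from D6/Zbtb20S mice and from wildtype littermates. Zbtb20 is a zinc finger transcriptional repressor of developing hippocampal pyramidal neurons, and the transgene places it in these areas, which the series' design text describes as transformed towards CA1, a hippocampal field. There were 3 arrays per genotype, each of RNA pooled from 7 animals. Arrays of one genotype were more alike than arrays of different genotypes: Pearson's r over all genes was 0.9943 to 0.9967 among wildtype arrays, 0.9961 to 0.9972 among D6/Zbtb20S arrays and 0.9884 to 0.9914 between genotypes. The first principal component held 60.0% of the variance and separated the genotypes, with wildtype arrays at -20.7, -21.7 and -14.4 and transgenic arrays at 20.1, 18.5 and 18.2. The second held 15.1% and ran from 14.6 in wildtype replicate 1 to -16.3 in wildtype replicate 3. In the same order of wildtype replicates the 3'-minus-5' signal of the actin control was 0.53, 0.88 and 1.31. That of the Gapdh control was -0.33, -0.03 and 0.30. Transgenic arrays spread less, from 0.80 to 0.91 for actin and from -0.023 to -0.002 for Gapdh.

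Zbtb20 itself was examined first, since the transgene carries it. Of 9 Zbtb20 probe sets, 1422064_a_at was 5.04-fold higher in transgenic tissue, with a log2 signal of 8.97 ± 0.11 (SD, n = 3) against 6.64 ± 0.92 (SD, n = 3) in wildtype, a difference of 2.33 ± 0.37 (limma adjusted p = 0.00904). The other 8 probe sets did not pass the threshold, with log2 differences from -0.37 to 0.85 and adjusted p from 0.169 to 0.945. The probe set with the highest signal, 1437598_at, which represents the gene in the counts that follow, read 8.34 ± 0.57 (SD, n = 3) in wildtype and 8.21 ± 0.09 (SD, n = 3) in transgenic tissue, and the sign of its difference (-0.14) turned to 0.18 without wildtype replicate 3. On all 9 probe sets wildtype replicate 3 lay above the other wildtype arrays, by a median of 1.06 against their mean. On 1422064_a_at it read 7.64, against 6.44 and 5.84 in the other wildtype arrays and 8.88, 9.10 and 8.94 in the transgenic ones. All 3 transgenic arrays lay above wildtype replicates 1 and 2 on 1437065_at, 1437066_at, 1438443_at and 1451577_at too, but not on the remaining sets. On 1451577_at wildtype replicates 1, 2 and 3 read 5.85, 5.71 and 7.20, and the transgenic arrays 6.80, 6.93 and 7.19. The positions of the probe sets in the transcript were not used here, and a probe set outside the transgene says nothing about the label of an array.

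**Figure D1:**
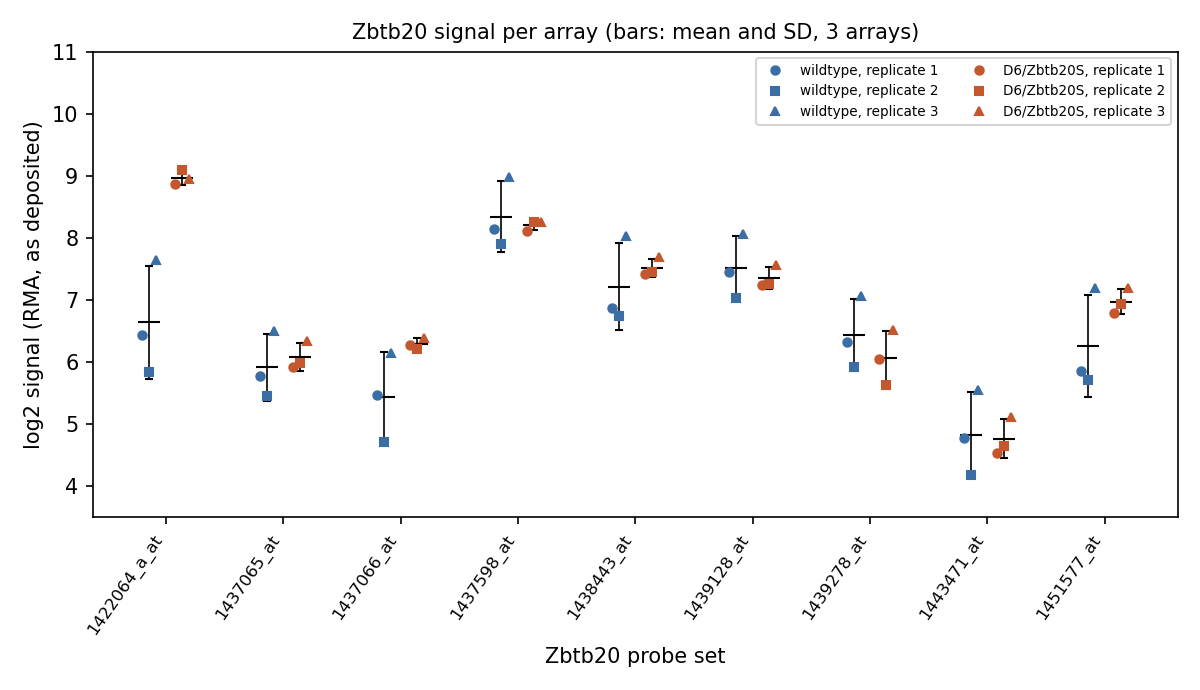
Log2 signal (y axis, RMA values as deposited) of the 9 Zbtb20 probe sets (x axis) in each of 3 wildtype (blue) and 3 D6/Zbtb20S (orange) arrays, with marker shape giving the replicate and black bars the mean and SD. Probe set 1422064_a_at lies at 8.88 to 9.10 in all 3 transgenic arrays and at 5.84 to 7.64 in wildtype, and wildtype replicate 3 (triangles) is the highest wildtype array on every probe set.

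Which genes changed in the transgenic areas was asked next. The largest changes were losses. Tshz2, a teashirt zinc finger transcription factor of retrosplenial cortex, was 18.3-fold lower in transgenic tissue (log2 change -4.20 ± 0.12, adjusted p = 2.8e-07, n = 3 and 3 arrays), and its relative Tshz3 was 9.90-fold lower. The anion exchanger Slc26a7 was 16.4-fold lower and the orphan nuclear receptor Nr4a2 was 10.1-fold lower. Among rises, the secretogranin gene Scg2 was 6.85-fold higher (2.78 ± 0.23, adjusted p = 7.8e-05), and the transcriptional repressor Bcl6 6.51-fold higher (2.70 ± 0.22, adjusted p = 7.3e-05). Scg2 and Bcl6 lost their calls with the ordinary linear model (adjusted p = 0.0618 and 0.0598). Of 107 named genes past the threshold, 41 kept their call in that model.

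Gastrin-releasing peptide (Grp) was 8.17-fold lower and neurotensin (Nts) 5.68-fold lower, while Inhbb, a subunit gene of activin B, was 4.04-fold higher. The AP-1 factor gene Fosl2 was 7.20-fold lower, with its other probe set not passing. The remaining falls among the 12 largest were Brinp3 (6.25-fold), Ccbe1 (6.22-fold), the unconventional myosin Myo5b (5.72-fold), 9130024F11Rik (5.10-fold) and the cell adhesion gene Cntn5 (4.97-fold). The remaining rises were Sertm1 (5.96-fold), the thyroid hormone-binding protein gene Crym (4.77-fold), 9530059O14Rik (4.66-fold), the tight junction gene Cldn1 (4.46-fold), Unc13c, a synaptic vesicle priming factor (4.04-fold), the guidance cue Sema3e (3.95-fold), the vasopressin receptor Avpr1a (3.94-fold), the microtubule-associated Map1b (3.92-fold) and the lipoprotein lipase gene Lpl (3.79-fold). In transgenic tissue Slc26a7, Brinp3, Myo5b and Cntn5 lay under the array median, and in wildtype tissue Cldn1 and 9530059O14Rik did, so these folds may be compressed. None of the 3 other Cldn1 probe sets passed, nor did the other probe set of Slc26a7, of Inhbb and of 9530059O14Rik. Crym, 9530059O14Rik, Sema3e, Map1b, Lpl and 9130024F11Rik lost their calls with the ordinary linear model (adjusted p from 0.0523 to 0.168).

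Of 18193 genes, 1402 (7.71%) differed between the genotypes at an adjusted p under 0.05 in limma, 739 of them higher and 663 lower in transgenic tissue. At least 2-fold, 264 genes changed, 110 higher and 154 lower. At least 4-fold, 8 genes were higher and 26 lower, and at least 8-fold, 0 were higher and 5 lower, namely Tshz2, Slc26a7, Nr4a2, Tshz3 and Grp. By probe set, 2484 passed, 1533 higher and 951 lower, of which 315 had no single gene name. Of the called genes, 863 had several probe sets, and 4 had another probe set called the opposite way. Both group means lay under the array median for 138 called genes. Without wildtype replicate 3, the array set apart by its Zbtb20 signal, 1539 genes passed (924 higher, 615 lower), 300 of them at least 2-fold (147 higher, 153 lower). The count fell to 777 without wildtype replicate 2 and to 836 without D6/Zbtb20S replicate 1, while the 2-fold count stayed between 255 and 300 whichever array was left out. It was 267 with the ordinary linear model and 2707 with array weights, counting genes of any fold.

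Some of the genes that mark the dissected areas fell in transgenic tissue: 4 of 8 in the subiculum list and 3 of 7 in the retrosplenial list. In the subiculum list 0 rose, and the genes that fell were Nts (11.3 to 8.78 on the log2 scale), fibronectin Fn1 (-1.41 ± 0.17), the adhesion gene Cntn6 (-1.38 ± 0.10) and the vesicular glutamate transporter gene Slc17a6 (-1.26 ± 0.17). The other Slc17a6 probe set did not pass, and as the mean of its probe sets Slc17a6 was at -0.57 and lost its call (adjusted p = 0.17). In the retrosplenial list Tshz2, Nr4a2 and the chemokine Cxcl14 (-1.62 ± 0.20, under the array median in transgenic tissue) fell, and 1 rose, Lypd1 (0.48 ± 0.12). Lypd1 missed the threshold in 4 of the 6 fits that left out 1 array (adjusted p up to 0.188) and as the mean of its probe sets (adjusted p = 0.106). The 4 fits were those without wildtype replicate 1 or 2 and without D6/Zbtb20S replicate 1 or 3. In the same comparison 4 of 12 microglial genes were higher (list median 0.40), and 4 of 11 oligodendrocyte (-0.25) and 2 of 15 GABAergic genes (-0.13) were lower. None of these 3 lists was called by camera with an estimated correlation (adjusted p of 0.232, 0.529 and 0.232). Adjusted over the list alone, 5 subiculum genes were lower and 3 retrosplenial genes lower with 1 higher. The subiculum list had a median change of -0.84 (camera adjusted p = 3.2e-05; adjusted p = 0.232 with an estimated correlation), and the retrosplenial list a median of -0.13 and a mean of -1.26 (camera adjusted p = 0.00172; adjusted p = 0.205 with an estimated correlation).

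Hippocampal markers went both ways. In the CA1 list 2 of 11 genes rose, the adhesion molecule Nectin3 by 3.70-fold (1.89 ± 0.10, adjusted p = 5.7e-06) and the mannosidase gene Man1a by 1.44-fold, and 2 fell, the chromatin organiser Satb1 (-1.19 ± 0.12) and the receptor kinase Tyro3 (-0.70 ± 0.11). Man1a lost its call without wildtype replicate 2 or D6/Zbtb20S replicate 1 (adjusted p up to 0.0564). There were 6 higher and 3 lower CA1 genes when adjusted over the list alone. The CA1 median was 0.20 and the list was not called by camera (adjusted p = 0.101), while fry, which asks whether the members move one way on balance, called it higher (adjusted p = 0.0135). In the CA3 and dentate gyrus list 0 of 14 rose and 2 fell, Cpne4 (-1.66 ± 0.14) and the RNA-binding protein gene Elavl2 (-0.48 ± 0.10), and adjusted over the list alone 3 were lower (camera adjusted p = 0.321). Elavl2 did not pass without wildtype replicate 2, D6/Zbtb20S replicate 1 or D6/Zbtb20S replicate 3 (adjusted p up to 0.0985). None of its 4 other probe sets passed, and as the mean of its probe sets Elavl2 was at -0.06 (adjusted p = 0.733). The CA3 and dentate gyrus list was called lower over bright probe sets only (adjusted p = 0.0274, mean -0.45). The median was 0.01 and the mean -0.20, so they differed in sign.

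Of 20 layer VI and subplate genes, 9 fell, 2 rose and 9 did not pass. The cell cycle inhibitor Rprm was 4.88-fold lower, the transcriptional cofactor Zfpm2 4.35-fold, the heparan sulfate sulfotransferase gene Hs3st4 3.19-fold, the corepressor Tle4 3.10-fold, the neurotensin receptor Ntsr1 2.93-fold and the T-box factor Tbr1 2.66-fold lower. Tmem163 (-1.25 ± 0.13), Ccn2 (-0.75 ± 0.09) and the forkhead gene Foxp2 (-0.59 ± 0.14) also fell, while Lmo3 (0.49 ± 0.10) and Ppp1r1b (0.44 ± 0.09, under the array median in wildtype tissue) rose. Beside these changes, 4 of 12 microglial genes were higher and 4 of 11 oligodendrocyte and 2 of 15 GABAergic genes lower (list medians 0.40, -0.25 and -0.13), in lists that camera did not call with an estimated correlation. The GABAergic list also lost its call in 3 other fits. The layer VI and subplate list had a median change of -0.25 (camera adjusted p = 1.7e-07; adjusted p = 0.205 with an estimated correlation), and adjusted over the list alone 9 were lower and 2 higher. None of the 5 other Foxp2 probe sets passed, nor did their mean with it (adjusted p = 0.163), and Foxp2 itself missed the threshold without wildtype replicate 2 or 3 or without D6/Zbtb20S replicate 2 or 3 (adjusted p up to 0.115). Lmo3 did so without D6/Zbtb20S replicate 1 or 2 (up to 0.0734), and Ppp1r1b without wildtype replicate 2 or D6/Zbtb20S replicate 1 (up to 0.0566).

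Layer V and upper-layer genes were mixed. In layer V, Crym rose 4.77-fold and the zinc finger gene Bcl11b 1.99-fold, while Crim1 (3.44-fold), the subcerebral projection neuron determinant Fezf2 (2.28-fold), the forkhead factor Foxo1 (1.95-fold), Cdh13 (1.78-fold) and Pcp4 (1.36-fold) fell, which made 2 higher and 5 lower of 15 (camera adjusted p = 0.0991). The layer V list was called lower without wildtype replicate 2 (adjusted p = 0.0382), over bright probe sets only (adjusted p = 0.0274) and by fry (adjusted p = 0.0136). Pcp4 lost its call without D6/Zbtb20S replicate 2 or 3 (adjusted p up to 0.057), and Foxo1 was read on a probe set of the _s_at type. In layers II-IV, 4 of 20 genes rose and 6 fell. The transcription factor Mef2c was 4.53-fold lower (-2.18 ± 0.07, adjusted p = 5.6e-07), and Dok5 (4.91-fold), the netrin receptor Unc5d (2.76-fold), Rasgrf2 (2.58-fold), Cux2 (1.74-fold) and Cux1 (1.27-fold) were lower, while the corepressors Tle1 (2.59-fold) and Tle3 (1.74-fold), the activin subunit Inhba (1.69-fold) and the LIM factor Lhx2 (1.40-fold) were higher. Dok5 lay under the array median in transgenic tissue. The upper-layer list had a median of 0.09 and a mean of -0.22, which differ in sign (camera adjusted p = 0.644; fry adjusted p = 0.00512, lower). None of the 8 other Cux1 probe sets passed, the mean of its probe sets did not (adjusted p = 0.144), and Cux1 lost its call without wildtype replicate 2, D6/Zbtb20S replicate 2 or D6/Zbtb20S replicate 3 (adjusted p up to 0.12) and with the replicate block (adjusted p = 0.057). Lhx2 lost its call without wildtype replicate 2, D6/Zbtb20S replicate 1 or D6/Zbtb20S replicate 2 (up to 0.0518). Adjusted over the list alone, 2 layer V genes were higher and 6 lower, and 5 upper-layer genes were higher and 7 lower.

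Of the 10 measured genes recalled as singled out by the study, 8 fell and 0 rose: Mef2c, Zfpm2, Tle4, Tbr1, Fezf2, Cux2, Foxp2 and Cux1. Their median change was -0.99 (camera adjusted p = 2.2e-12; adjusted p = 0.205 with an estimated correlation), and the same 8 of 10 count held when adjusted over the list alone. The list was written from memory of the study and may not match it exactly. As the study may have chosen these genes on these arrays, neither count is taken as independent evidence of their direction, nor are the layer lists that hold them. Over the 3 layer lists, 8 of 55 genes rose and 20 fell, and without the study's genes 8 of 45 rose and 12 fell.

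**Figure D2:**
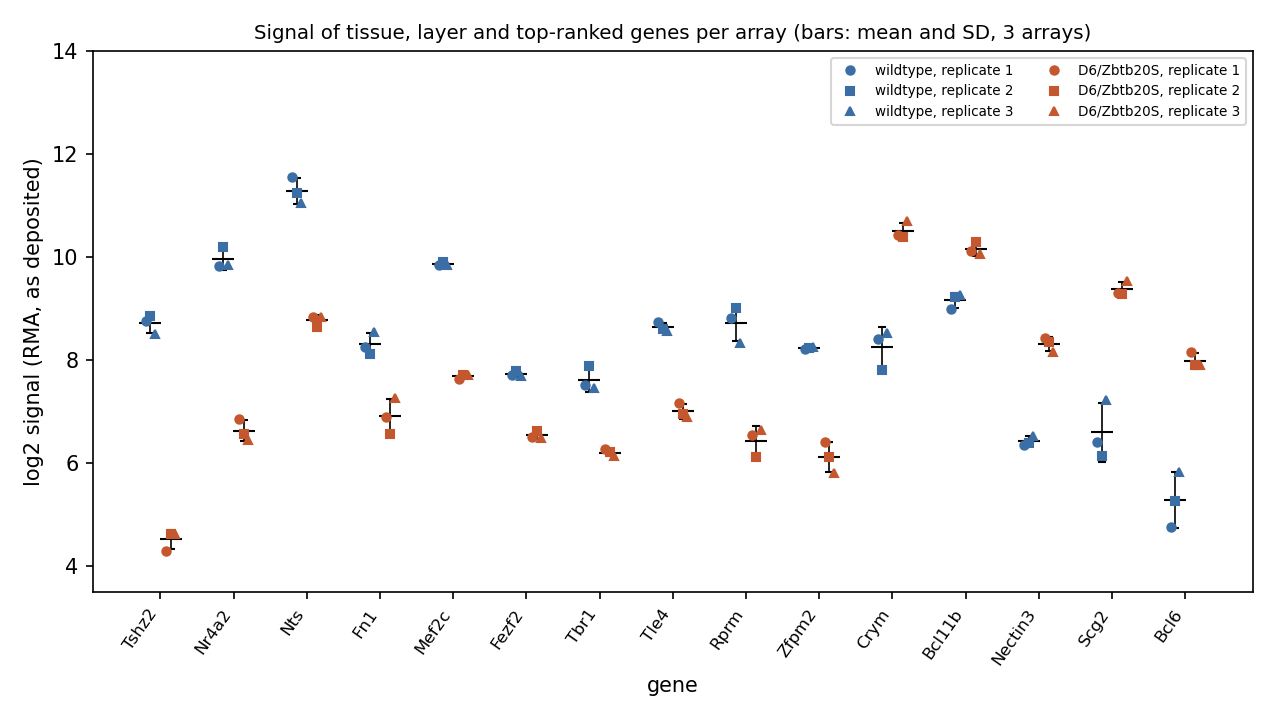
Log2 signal (y axis, RMA values as deposited) of 15 genes (x axis) in each of 3 wildtype (blue) and 3 D6/Zbtb20S (orange) arrays, with black bars for the mean and SD. Tshz2 falls from a mean of 8.72 to 4.52 and Tbr1 from 7.62 to 6.21, while Crym rises from 8.25 to 10.5 and Nectin3 from 6.43 to 8.32.

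All 12 measured microglial genes had positive changes (median 0.40, camera adjusted p = 9.3e-07; adjusted p = 0.232 with an estimated correlation), and 4 passed: the fractalkine receptor Cx3cr1 (0.87 ± 0.16), the adaptor Tyrobp (0.69 ± 0.11), Fcrls (0.55 ± 0.13) and the protease Ctss (0.49 ± 0.09). In all, 8 microglial genes were higher when adjusted over the list alone. Fcrls missed the threshold without wildtype replicate 1 or 2 or D6/Zbtb20S replicate 1 or 3 (adjusted p up to 0.125). In the oligodendrocyte lineage 4 of 11 genes fell, the lineage factors Olig2 (-0.77 ± 0.11) and Olig1 (-0.68 ± 0.08) and the myelin genes Cnp (-0.53 ± 0.10) and Mbp (-0.51 ± 0.08), with a list median of -0.25 (camera adjusted p = 0.000731; adjusted p = 0.529 with an estimated correlation). Of 15 GABAergic genes 2 fell, the GABA-synthesising enzyme Gad1 (-0.60 ± 0.10) and Nxph1 (-0.55 ± 0.13). The GABAergic list (median -0.13, camera adjusted p = 0.0302; adjusted p = 0.232 with an estimated correlation) was not called without wildtype replicate 3 (adjusted p = 0.0569) or without D6/Zbtb20S replicate 3 (adjusted p = 0.117), nor with the mean of probe sets (adjusted p = 0.0539). Nxph1 passed in 2 of the 6 fits with an array left out, those without wildtype replicate 3 and D6/Zbtb20S replicate 2. Adjusted over the list alone, 5 oligodendrocyte and 2 GABAergic genes were lower.

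Intermediate progenitor genes went both ways. Of 11, the transcription factor Eomes (-1.11 ± 0.21) and the somatostatin receptor Sstr2 (-0.94 ± 0.15) fell, and the proneural factor Neurog2 (0.87 ± 0.16) rose (camera adjusted p = 0.321). The progenitor list was called lower without wildtype replicate 2 (adjusted p = 0.0422), where its mean was -0.26 against -0.15 over all arrays. Without wildtype replicate 3 the mean was -0.054 (adjusted p = 0.692) and with array weights 0.00037 (adjusted p = 0.897). Eomes lost its call without D6/Zbtb20S replicate 3 (adjusted p = 0.0533) and Neurog2 without D6/Zbtb20S replicate 1 (adjusted p = 0.0564). Of 18 radial glia and astrocyte genes 1 fell, Sox2 (-0.42 ± 0.11), and of 14 endothelial and mural genes 1 fell, the glucose transporter gene Slc2a1 (-0.36 ± 0.08). Sox2 passed in 2 and Slc2a1 in 1 of the 6 fits with an array left out: Sox2 without wildtype replicate 1 or D6/Zbtb20S replicate 1, and Slc2a1 without wildtype replicate 1. Sox2 also lost its call with the replicate block (adjusted p = 0.0717). No Cajal-Retzius (10 measured), red blood cell (7), choroid plexus (10) or meningeal (12) gene passed in limma; at an unadjusted p under 0.05, 4, 1, 1 and 1 of them did. The smallest p in these lists belonged to Lhx5 (-0.24, adjusted p = 0.117), Hba-a2 (0.43, adjusted p = 0.059), Calml4 (0.46, adjusted p = 0.187) and Ptgds (-0.65, adjusted p = 0.229), with Lhx5, Hba-a2 and Calml4 under the array median in both groups. Adjusted over the list alone, 1 progenitor gene was higher and 3 lower, 0 radial glia and astrocyte genes passed, 1 endothelial and mural gene was lower and 1 red blood cell gene was higher. None of these 6 lists of glia, vessels, blood, choroid plexus, meninges and Cajal-Retzius cells was called by camera (adjusted p from 0.571 to 0.973).

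Markers of neighbouring regions were also read. In the thalamus list 1 of 10 fell, Slc17a6, which the subiculum list also holds and which lost its call as the mean of its probe sets (camera adjusted p = 0.499). In the striatum list 3 of 9 rose and 0 fell: the forkhead factor Foxp1 by 2.18-fold (1.12 ± 0.09, with all 7 of its other probe sets called the same way), the enkephalin precursor Penk by 1.58-fold and Ppp1r1b by 1.35-fold. The other 6 members, which include the dopamine receptor genes Drd1 (0.05) and Drd2 (0.004), did not pass. Ppp1r1b is also in the layer VI and subplate list. The striatum list had a median of 0.09 (camera adjusted p = 0.00742, and 0.398 with an estimated correlation). Penk lost its call without wildtype replicate 2 or D6/Zbtb20S replicate 1 (adjusted p up to 0.0516), as Ppp1r1b did. With p-values adjusted over the list alone, 1 thalamus gene was higher and 1 lower, and 3 striatum genes were higher. Of 4 sex-linked genes 1 fell, the Y-linked Eif2s3y (-0.46 ± 0.09).

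Genes of axon guidance, adhesion and neuronal signalling changed in both directions. Of 55 axon guidance genes 11 rose and 8 fell, among them Sema3e and the netrin receptor Dcc (2.54-fold higher) and Unc5d and Robo3 (2.82-fold lower, under the array median in transgenic tissue). Of 29 cadherins 5 rose and 10 fell, with Cdh6 (2.74-fold), Pcdh17 (2.52-fold) and Cdh9 (2.19-fold) lower. The cadherin list (median -0.12, camera adjusted p = 0.0345; adjusted p = 0.585 with an estimated correlation) was not called without wildtype replicate 3 (adjusted p = 0.239) or D6/Zbtb20S replicate 3 (adjusted p = 0.162), nor with array weights (0.0661), over bright probe sets only (0.108) or by fry (0.0759). Pcdh17 lost its call as the mean of its probe sets (-0.98, adjusted p = 0.0751). Of 35 Wnt signalling genes 4 rose and 6 fell, including the secreted Rspo2 (4.01-fold lower) and Dkk3 (3.14-fold lower) and the receptor Fzd7 (2.11-fold higher). Among 21 glutamate receptor genes 3 rose and 4 fell: Grin3a (2.58-fold) and Grm5 (2.41-fold) were higher, and Grm2 (2.79-fold) and Grik3 (2.37-fold) lower. Of 10 GABA-A receptor genes 2 fell, Gabrg1 (2.02-fold) and Gabrb2 (1.44-fold). None of the 4 other Gabrb2 probe sets passed, and as the mean of its probe sets Gabrb2 was at -0.27 (adjusted p = 0.115). Of 43 potassium channel genes 1 rose, Kcnd2 (2.52-fold), and 7 fell, including Kcnq5 (3.08-fold) and Kcnip1 (1.91-fold). Adjusted over the list alone, the higher and lower counts were 16 and 10 for axon guidance, 7 and 14 for cadherins, 4 and 8 for Wnt signalling, 4 and 4 for glutamate receptors, 1 and 3 for GABA-A receptors and 6 and 11 for potassium channels. The axon guidance, Wnt, glutamate receptor, GABA-A receptor and potassium channel lists were not called by camera (adjusted p of 0.233, 0.0694, 0.844, 0.505 and 0.0639). The Wnt list was called without wildtype replicate 1 (adjusted p = 0.0293), wildtype replicate 2 (0.0364) or D6/Zbtb20S replicate 1 (0.0202), over bright probe sets only (0.0274) and by fry (0.0288). The potassium channel list was called without wildtype replicate 1 (0.00501) or D6/Zbtb20S replicate 3 (0.0316), with quantile normalization (0.0327), with array weights (0.0451) and over bright probe sets only (0.045), and the axon guidance list, higher, with the mean of probe sets (0.0206).

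Of 25 cell cycle genes 1 fell, the ribonucleotide reductase gene Rrm2 (-0.56 ± 0.11), which lost its call without D6/Zbtb20S replicate 2 (adjusted p = 0.0512). The cell cycle list had a median of -0.21 (camera adjusted p = 0.0473, and 0.807 with an estimated correlation). It was not called without wildtype replicate 3 (adjusted p = 0.692) or D6/Zbtb20S replicate 2 (adjusted p = 0.258). Nor was it called with array weights (0.497) or by fry (0.502). It holds none of the study's genes. With those genes removed its adjusted p was 0.0508 only because the study's list left the adjustment, which then ran over 28 lists. Immediate early genes had 1 rise, Egr2 (1.22 ± 0.21, under the array median in both groups), and 1 fall, Nr4a1 (-0.50 ± 0.08), of 15. Of 13 chaperone and stress genes 2 rose, including the heat shock gene Hspa1b (0.69 ± 0.12), and 2 fell. Neither list was called by camera (adjusted p = 0.762 and 0.394). When p-values were adjusted over the list alone, 1 cell cycle gene was lower, 1 immediate early gene was higher and 1 lower, and 3 chaperone and stress genes were higher and 2 lower.

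In all, camera called 10 of 29 lists at the preset correlation, 8 lower and 2 higher, and 0 with an estimated correlation, while fry called 12. Of the genes named from the lists, no other probe set passed for Tyro3, Cpne4, Rasgrf2, Cux2, Inhba, Eomes, Cnp, Gad1, Nxph1, Cx3cr1, Slc2a1, Robo3, Grik3, Cdh6, Pcdh17, Rspo2, Fzd7 and Eif2s3y, each of which had at least 1. Groupings of the 6 arrays that mix the genotypes gave up to 12 called lists by camera. At an unadjusted p under 0.05 with an estimated correlation, 6 lists passed.

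**Figure D3:**
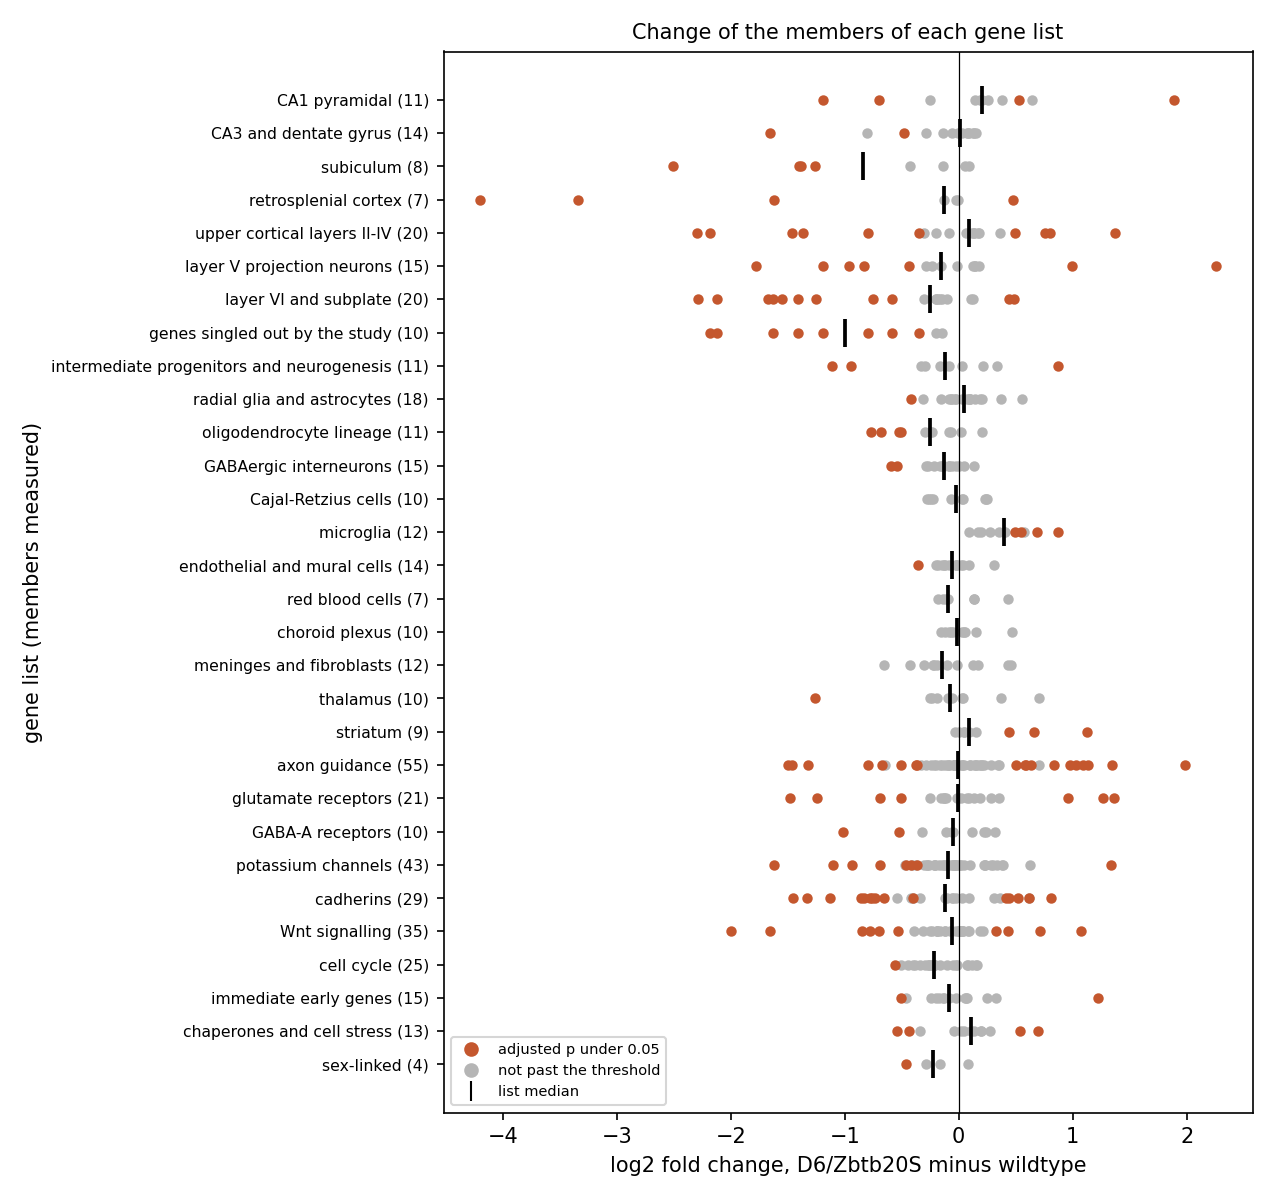
Log2 fold change (x axis, D6/Zbtb20S minus wildtype) of every measured member of the 30 gene lists (y axis, members measured in brackets), with genes at an adjusted p under 0.05 in orange, others in grey and a black mark for the list median. The study, subiculum and layer VI lists have medians of -0.99, -0.84 and -0.25, and all 12 microglial genes lie above 0.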

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

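The tests of wildtype replicate 3, of the microglial genes and of the Zbtb20 probe sets were chosen after the results were seen; the splits of the arrays were planned.

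With 6 arrays there are 10 ways to split them 3 against 3, too few for a share under 5%. The genotypes gave 1402 genes, 264 genes at least 2-fold changed and 2484 probe sets, and the highest of the other splits gave 0 of each in limma, so 1 of the 10 splits reached each count. At an unadjusted p under 0.05 the genotypes gave 3694 genes and the other splits 192 to 1166, and for probe sets 7962 against 538 to 2672. For the gene lists the genotypes gave 10 called lists and the highest other split 12, and 3 of the 10 splits gave at least 10.

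Wildtype replicate 3 had more Zbtb20 signal than the other wildtype arrays on 9 of 9 probe sets, by a median of 1.06. RNA of transgenic tissue in that pool cannot be told apart. A mixture cannot exceed both parts, and the array lay above all 3 transgenic arrays on 7 probe sets, but by a median of 0.42, within a bound of 0.51 for 2 single arrays. For genes at least 2-fold higher in transgenic tissue the array had covered a median of 24.7% of the log2 change, and for genes at least 2-fold lower 3.13%. Hippocampal tissue in the pool stays open. The CA3 and dentate gyrus list had a median shift of -0.012 there, at the 46th percentile of random lists of the same size and similar mean signal. Its members went both ways. Prox1 was at 0.96 and C1ql3 at 0.90, and Neurod1 of the progenitor list was at 0.89. The choroid plexus gene Ttr was higher still, at 1.24, but the choroid plexus list had a median shift of -0.038. RNA degradation cannot be told apart either, since actin 3'-minus-5' signal (0.53, 0.88 and 1.31 in wildtype replicates 1, 2 and 3) ranks replicate 1 lowest while replicate 1 exceeded replicate 2 in Zbtb20 by a median of 0.40, within the same bound. The meningeal list was shifted by 0.47 and the cell cycle list by 0.32 in the same array. Other lists moved there too, among them the endothelial and mural (0.27), cadherin (0.19) and radial glia and astrocyte (0.19) lists. The layer VI and subplate list (-0.082) and the microglia list (-0.048) lay below 0. A biological difference between the wildtype pools was not tested.

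Of 12 microglial genes 4 were higher in transgenic tissue and 8 did not pass, with a list median of 0.40, and the list was not called by camera with an estimated correlation (adjusted p = 0.232). A lower share of the main cell type would raise markers of other cell types alike, and the endothelial and mural list had a median of -0.056 with an SD of 0.16 over its members. With equal array medians the microglial median was 0.38. The array medians averaged 3.87 in wildtype and 3.89 in transgenic tissue, so this step could hardly change it. It therefore does not decide whether scaling plays a part. More microglia, or microglia in another state, in the transgenic tissue may remain as a hypothesis that these data do not separate, and dissection and the pools' litters stay open. Counts of microglia in sections, or profiles of sorted microglia, would separate number from state.

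Of the 9 Zbtb20 probe sets 1 passed the threshold, although the transgene carries Zbtb20. Wildtype replicate 3 bears on this count. On 1437065_at, 1437066_at, 1438443_at and 1451577_at all 3 transgenic arrays also lay above wildtype replicates 1 and 2, and on the remaining sets they did not. A candidate explanation is that the transgene holds only part of the Zbtb20 transcript, so that 1 probe set reads it and the others read the endogenous gene. Whether it does cannot be told apart here from lower endogenous expression or from differences between probe sets, because the positions of the probe sets were not used.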

How the results depend on the processing

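All alternatives were fixed beforehand. The count of 1402 genes (739 higher, 663 lower; 2484 probe sets) rose to 2707 (1404 higher, 1303 lower; 4710 probe sets) with array weights. It was 693 (328 higher, 365 lower; 1062 probe sets) at a threshold of 0.01 and 2062 (1131 higher) at 0.1, by construction. With the ordinary linear model, which does not pool the spread over genes, it was 267 (117 higher, 150 lower; 200 probe sets). With 1 array left out it ranged from 777 to 1539 (379 to 924 higher, 398 to 630 lower, 1162 to 2881 probe sets), on fewer samples. Median scaling and quantile normalization gave 1512 and 1557 genes. Averaging a gene's probe sets left 102 genes at least 2-fold lower instead of 154; the cause was not tested. The Zbtb20 difference of -0.14 turned to 0.12 with array weights, and the cause of that turn was not tested. As the mean of probe sets, which takes in the 2.33 of 1422064_a_at, it was 0.40. With 1 array left out it ranged from -0.36 to 0.18. The 0.18 came without wildtype replicate 3, which read 8.98 on 1437598_at against 8.15 and 7.90 in the other wildtype arrays. In none of these fits did the Zbtb20 difference pass. Probe set 1422064_a_at stayed higher and past the threshold with the replicate block, each array left out and both scalings. It also did so with array weights, an intensity trend and bright probe sets only. Its result in the ordinary linear model was not read. Lists called went from 10 to 0 with an estimated correlation and from 7 to 13 with 1 array left out. For the retrosplenial and GABAergic lists the estimate was -0.12 and -0.03, under the preset 0.01. Their unadjusted camera p still rose, from 0.000355 to 0.0213 and from 0.00834 to 0.048. A higher correlation thus does not account for those losses, while the other called lists had estimates above the preset. With an estimated correlation camera also takes its degrees of freedom from the 6 arrays instead of the genes, which raises p for every list. The smallest unadjusted camera p with an estimated correlation was 0.0147. Over the alternatives the 10 called lists kept their call 135 times and lost it 23 times, with no called list turning direction, and uncalled lists gained a call 18 times. Array weights ended the cadherin (adjusted p = 0.0661) and cell cycle (adjusted p = 0.497) calls. The first component held 84.4% of the variance over the 1000 most variable genes and 66.0% over bright probe sets. With the replicate block, 1343 genes passed, 1195 of them shared, and 3304 probe sets passed against 2484. Deviations of same-numbered arrays correlated at -0.22, 0.18 and -0.01. Only the arrays numbered 2 correlated better with each other than with another number (0.18 against -0.02). With so few arrays per group, these correlations cannot decide whether the numbers pair the arrays. Whether they do stays unknown. Of 107 named genes past the threshold, 86 kept their call whichever array was left out. With the ordinary linear model 41 kept it, and 98 did in all other alternatives in which they were tested. The thresholds of 0.01 and 0.1 were not among these alternatives for single genes. In any fit, 0 changed direction. All 1402 called genes had arrays that did not overlap between groups, so leaving out or weighting arrays could not turn a direction. Low signal limits the folds of genes under the array median.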

Other observations

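The gene families below were chosen after the values were seen, from genes near the top of the ranking, so their counts are descriptions and not tests. Adhesion genes of the contactin family fell: of 6 measured, Cntn5 (4.97-fold), Cntn4 (3.61-fold), Cntn6 (2.60-fold) and Cntn1 (1.42-fold) were lower in transgenic tissue and 0 were higher. Of 3 teashirt genes 2 fell, Tshz2 and Tshz3, and of 3 BRINP genes 2 fell, Brinp3 (6.25-fold) and Brinp1 (2.57-fold). Tenm3, a teneurin that guides hippocampal and visual wiring, was 4.42-fold lower, alone among 4 measured teneurins.

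The LRRTM family of postsynaptic adhesion proteins split: Lrrtm1 (2.50-fold) and Lrrtm2 (1.49-fold) were higher, and Lrrtm4 and Lrrtm3 lower. In transgenic tissue Lrrtm4, Lrrtm3, Cntn5 and Brinp3 lay under the array median, so their folds are uncertain. Of 3 neuroligins Nlgn1 was 2.93-fold higher. Of 5 activin and inhibin subunit genes Inhbb (4.04-fold) and Inhba (1.69-fold) were higher. Among 6 glypicans Gpc5 was 2.57-fold higher and Gpc4 1.32-fold lower, and among 9 calmodulin-dependent kinase genes Camk2a (1.57-fold) and Camk1d (1.41-fold) were higher and Camk4 3.17-fold lower. The kinase family was narrowed to kinase genes after a wider set that included inhibitor genes had been seen. The 9 families counted held 43 measured genes, 8 higher and 13 lower. Each of the 21 calls kept its direction and threshold under median scaling and quantile normalization. This is a weak check, since the deposited array medians already averaged 3.87 in wildtype and 3.89 in transgenic tissue. Lrrtm2, Gpc4 and Camk2a had adjusted p of 0.024, 0.025 and 0.022 in limma, and fits with an array left out are not given for them.

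Of the array's 64 control probe sets 0 passed in limma when adjusted among themselves, and 3 had an unadjusted p under 0.05.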
